A study of Callithrix jacchus with 39 samples.

How the data were processed

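ChIP-seq of H3K27ac (antibody ab4729) and H3K4me3 (ab8580) was carried out on 8 marmoset tissues, and DNA libraries were made with a TruSeq DNA kit, per the labels' protocols. The submitters' processing notes name Bowtie 1.1.2, SAMtools 1.3.1, MACS2 2.1.1.20160309 and bedtools 2.26 without a role or order. The deposited files are peak lists in narrowPeak form, 1 per ChIP library, so peaks were called per sample and not on pooled replicates. Peak names in all 31 lists carry the strings 1e-5, exts300, ll100000 and calJac3, from which the genome build was taken as calJac3. How the input samples were used is not given in the sources used here. In each list the deposited score column is the −log10 p multiplied by 10 and truncated in nearly all peaks. The deposited fold enrichment is a ratio set by the authors' peak caller. The deposited −log10 p and −log10 q columns had lowest values of 5.09 and 3.04 over all lists. No peak was shorter than 300 bp, and no peaks of 1 list overlapped or touched. Fold enrichment is the authors' value and was used only to rank or group peaks within 1 list. Read totals are not used here, so depth per library is unknown. A deeper or more enriched library yields a longer list, which limits any comparison of list length.

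Libraries were grouped by the tissue, mark and replicate number in their titles. Intervals were handled with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Overlap meant at least 1 bp. Reproducible regions were those of either replicate overlapped by the other, merged. Restricted regions were reproducible regions with no overlap in any H3K27ac library of the 7 other tissues. As background, regions were also moved along their own chromosome by 20 distances from 5 to 24 Mb. The Jaccard index of replicates lay between 0.467 and 0.735, so none was a duplicate of another. Differences between marks or classes were tested over tissues with exact sign-flip permutation tests, and similarity with 100000 relabellings of libraries or all 210 arrangements of the related tissue pairs, all two-sided. Benjamini-Hochberg adjustment covered the 10 planned comparisons. The interval and test code was tested on simulated data before use. For the replicate overlap of enhancer-like and promoter-like regions, 10000 regions per library were simulated, and only replicate 1 regions were scored against replicate 2. A set difference of -40 points was recovered as -39.4, and 2 of 40 simulations without a difference gave p under 0.05. The mean of both directions, which is reported below, was not scored in the simulation, so its error rate was not measured.

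The comparisons, their tests, the classes and the rule for named clusters (the 3 largest per tissue by covered length of restricted regions joined within 12 kb) were fixed before the data were examined. So were these alternatives: peaks with −log10 q of at least 5, the 20000 strongest peaks per list, assembled chromosomes alone, overlap of at least 50%, matching within 10 strata of fold enrichment, lists of equal length (16386 peaks), H3K4me3 required in every library of the tissue, the replicate number as a block, and leaving out each library. The comparisons of catalogue breadth, region length and H3K4me3 without H3K27ac were added after the data were examined, and their p-values are not adjusted. The 25 gene lists fixed beforehand were not tested, because no gene annotation of calJac3 was used here and the gene tables at hand describe another assembly. No coordinate was converted between builds, no peak was assigned to a gene, and the planned count of tissue-restricted genes was made on 100 kb windows, the substitute fixed for that case.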

Results

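The series profiled 2 histone marks by ChIP-seq in 8 tissues of the common marmoset (Callithrix jacchus), a small New World monkey. H3K27ac is an acetylation found at active promoters and enhancers, and H3K4me3 is a methylation found mainly at promoters. Colon, heart, kidney, liver, pancreas, skeletal muscle, spleen and stomach each had 2 numbered replicates per mark, except heart, which had 1 H3K4me3 library (replicate 2). The 31 ChIP libraries comprised 16 for H3K27ac and 15 for H3K4me3, and the series also lists 8 input samples, which are not analysed here. Each ChIP library was represented by its own peak list. Read depth behind the lists is unknown, so no interval or detection floor was computed, and absence from a list means only that no peak was called. The labels do not say whether replicate numbers stand for different animals. The p-values therefore measure the spread between these samples, or between tissues, and not the spread between individuals. The title of the series names variability between individuals and recently emerged enhancers, and the comparisons below address how stable peak maps were between replicates and how far they were shared between tissues.

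The H3K27ac maps held more regions than the H3K4me3 maps in all 8 tissues. H3K27ac lists ranged from 24590 peaks (heart, replicate 2) to 51554 peaks (liver, replicate 2), with a mean over tissues of 35396 ± 6808 (SD, n = 8). H3K4me3 lists ranged from 16386 peaks (pancreas, replicate 1) to 24424 peaks (skeletal muscle, replicate 2), with a mean of 20269 ± 1660 (SD, n = 8). Peak number was 1.72-fold higher for H3K27ac (log2 ratio 0.79 ± 0.23, SD, n = 8; two-sided exact sign-flip permutation test, p = 0.00781, adjusted p = 0.0112). H3K27ac covered 27.9 ± 7.88 Mb and H3K4me3 19.5 ± 3.06 Mb (SD, n = 8), 1.40-fold more for H3K27ac (log2 ratio 0.49 ± 0.28, SD, n = 8; exact permutation test, p = 0.00781, adjusted p = 0.0112). Individual H3K27ac regions were shorter, with a mean length of 778 ± 71.6 bp against 950 ± 80.5 bp for H3K4me3 (SD, n = 8). Liver carried the widest H3K27ac coverage, 40.5 Mb and 47.4 Mb in its replicates, and heart the narrowest, 17.1 Mb and 17.8 Mb. The value 0.00781 is the smallest p that the 256 sign patterns of 8 tissues allow. When each list was reduced to its 20000 strongest peaks, which sets most lists to one length, the difference in peak number was 0.07 on the log2 scale (exact permutation test, n = 8, p = 0.0625) and that in covered length was 0.11 (p = 0.148).

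H3K4me3 regions recurred between the replicates of a tissue more often than H3K27ac regions. In the 7 tissues with replicates of both marks, 71.5 ± 3.67% of H3K27ac regions and 84.8 ± 3.96% of H3K4me3 regions were overlapped by a region of the other replicate (SD, n = 7). The difference was -13.3 ± 5.13 percentage points and had the same sign in 7 of 7 tissues (two-sided exact sign-flip permutation test, p = 0.0156, adjusted p = 0.0173). The p of 0.0156 is the smallest that 7 tissues allow. Against libraries of other tissues the overlap was 47.0 ± 6.82% for H3K27ac and 80.0 ± 4.97% for H3K4me3, and after regions were shifted along their own chromosome it was 2.12 ± 0.47% and 1.50 ± 0.20% (SD, n = 7). In 3 of 7 tissues H3K4me3 regions overlapped other tissues more often than their own replicate: pancreas (84.6% against 81.7%), skeletal muscle (80.9% against 77.6%) and spleen (87.5% against 85.6%). In H3K27ac this was so in 0 of 8. Such shares can rise with the length of the list compared against, and the H3K4me3 lists of spleen were short, at 16946 and 18658 peaks. H3K4me3 replicate overlap was lowest in skeletal muscle (77.6%) and pancreas (81.7%), whose replicate 1 lists were also the shortest of the mark at 16850 and 16386 peaks. In skeletal muscle 96.1% of replicate 1 regions were found in replicate 2 but 59.1% in the opposite direction, and in pancreas the values were 98.6% and 64.8%. Without these 2 short lists the difference between marks was -14.9 points in the remaining 5 tissues, where the exact permutation test cannot go below p = 0.0625.

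Among H3K27ac regions, those that carried no H3K4me3 were far less often shared between replicates. H3K27ac regions overlapping an H3K4me3 region of any library of the same tissue are called promoter-like here, and the remainder enhancer-like. The names refer to this rule alone. Because a promoter-like region must be met by a peak of a second ChIP, H3K27ac peaks called in error fall mostly among the enhancer-like regions. Across tissues 89.0 ± 1.54% of promoter-like regions and 55.2 ± 7.04% of enhancer-like regions were overlapped by the other replicate (SD, n = 8). The enhancer-like minus promoter-like difference was -33.9 ± 6.27 percentage points, below 0 in 8 of 8 tissues (two-sided exact sign-flip permutation test, p = 0.00781, adjusted p = 0.0112). The tissue means of promoter-like regions lay between 85.8% (kidney) and 90.9% (colon), whereas those of enhancer-like regions lay between 44.2% (heart) and 65.0% (colon). Colon, liver, skeletal muscle and stomach had enhancer-like overlaps of 65.0%, 61.6%, 59.4% and 58.5%. Spleen and pancreas had 51.9% and 50.7%, and kidney lay between pancreas and heart. Within deciles of the authors' fold enrichment, where regions of similar strength were compared, the shares were 81.9 ± 1.61% and 65.3 ± 5.63%, and the difference was reduced to -16.6 points (exact permutation test, n = 8, p = 0.00781).

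**Figure D1:**
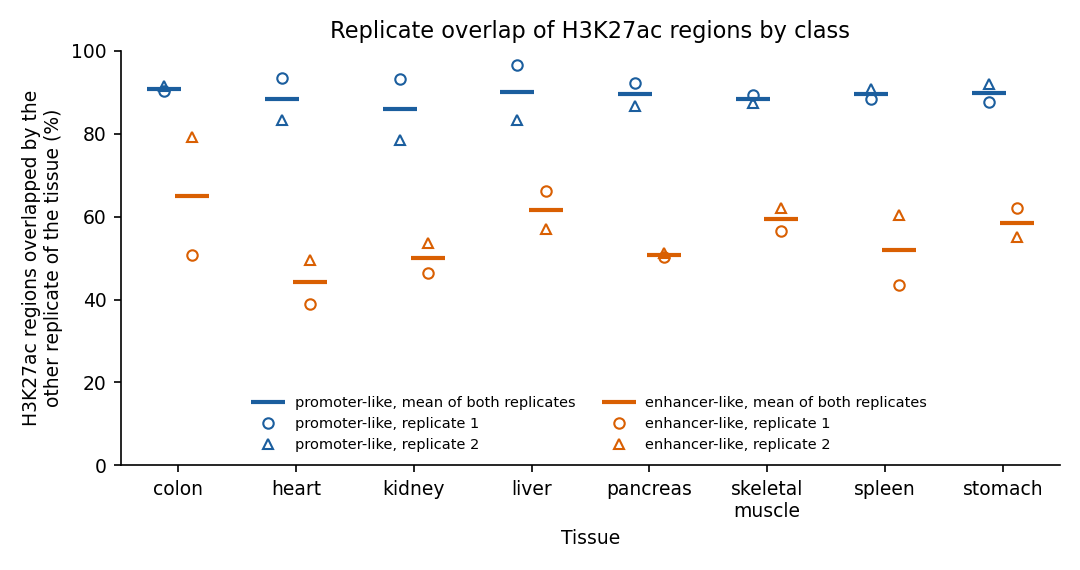
Percent of H3K27ac regions (vertical axis) that were overlapped by the other replicate of the same tissue, for promoter-like regions (blue) and enhancer-like regions (orange) in 8 tissues (horizontal axis). Bars are the mean of both replicates, circles replicate 1 and triangles replicate 2. The promoter-like means lie between 85.8% and 90.9% and the enhancer-like means between 44.2% and 65.0%.

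Enhancer-like regions were also much more restricted to 1 tissue than promoter-like regions. Regions found in both replicates of a tissue numbered 22767 ± 4677 per tissue (SD, n = 8), of which 39.2 ± 6.66% were enhancer-like. Of the enhancer-like regions 25.8 ± 14.1% were overlapped by no H3K27ac region in any library of the 7 other tissues, against 2.21 ± 1.95% of promoter-like regions (SD, n = 8). The difference was 23.6 ± 12.4 percentage points and positive in 8 of 8 tissues (two-sided exact sign-flip permutation test, p = 0.00781, adjusted p = 0.0112). Skeletal muscle (46.6%), liver (41.3%) and colon (36.2%) had the highest enhancer-like restricted shares. Spleen (23.8%), kidney (20.9%), pancreas (18.3%) and stomach (12.3%) followed, and heart, with the shortest lists, had 7.32%. Promoter-like restricted shares ranged from 0.25% in heart to 5.97% in liver. Matched for strength, the means were 22.8 ± 13.7% and 3.41 ± 3.11% (SD, n = 8). Promoter-like regions were longer, by a median of 352 ± 87.8 bp in 8 of 8 tissues (SD, n = 8; exact permutation test, p = 0.00781), and by 177.5 bp with the 20000 strongest peaks of each list (exact permutation test, n = 8, p = 0.00781). Longer regions meet an overlap of 1 bp more easily, so part of this length difference may follow from the class rule.

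The reproducible H3K27ac regions of all tissues merged into a catalogue of 65161 regions, 41524 of them enhancer-like and 23637 promoter-like. With the 20000 strongest peaks of each list it held 34659 regions, of which 46.4% were enhancer-like. In this catalogue a region counted as promoter-like if any H3K4me3 library of any tissue overlapped it. Merging made regions of more tissues longer (median 783 bp in 1 tissue, 2059 bp in all 8), and longer regions meet this rule more easily, so part of the class contrast in the catalogue could follow from its construction. A tissue counted only where the region was found in both replicates. Replicate overlap within tissues was 55.2% for enhancer-like and 89.0% for promoter-like regions, so part of the contrast in breadth could follow from it. The checks below keep this rule and do not address it. Of the enhancer-like regions 78.1% were reproducible in 1 tissue and 0.12%, or 51 regions, in all 8. Of the promoter-like regions 24.4% were found in 1 tissue and 31.3%, or 7391 regions, in all 8. With catalogue regions classed from their central 300 bp instead, 76.6% of enhancer-like and 23.6% of promoter-like regions were found in 1 tissue. In all 8 the shares were 0.48% and 32.9%, so the class contrast changed little. The shares were also taken on the central 300 bp of each tissue's own reproducible regions, merged between replicates but not between tissues. They were classed with H3K4me3 of the same tissue, and the regions they were compared with kept their full length. Of these, 41.5 ± 17.5% of enhancer-like and 4.56 ± 3.20% of promoter-like regions were found in 1 tissue (SD, n = 8; exact permutation test, p = 0.00781), and 3.53 ± 3.34% and 55.4 ± 7.08% in all 8 (SD, n = 8; exact permutation test, p = 0.00781). H3K4me3 regions, catalogued in the same way with the single heart library taken as it stood, numbered 23034, of which 45.6% were found in all 8 tissues and 20.7% in 1. H3K4me3 regions shared by all tissues were the broader ones. Measured on each tissue's own regions, their median length was 1323 ± 196 bp, against 696 ± 211 bp for those of 1 tissue (SD, n = 8), a difference of 627 ± 205 bp in 8 of 8 tissues (exact permutation test, p = 0.00781). Longer regions overlap those of other tissues more easily, so part of this length difference may follow from the overlap rule.

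**Figure D2:**
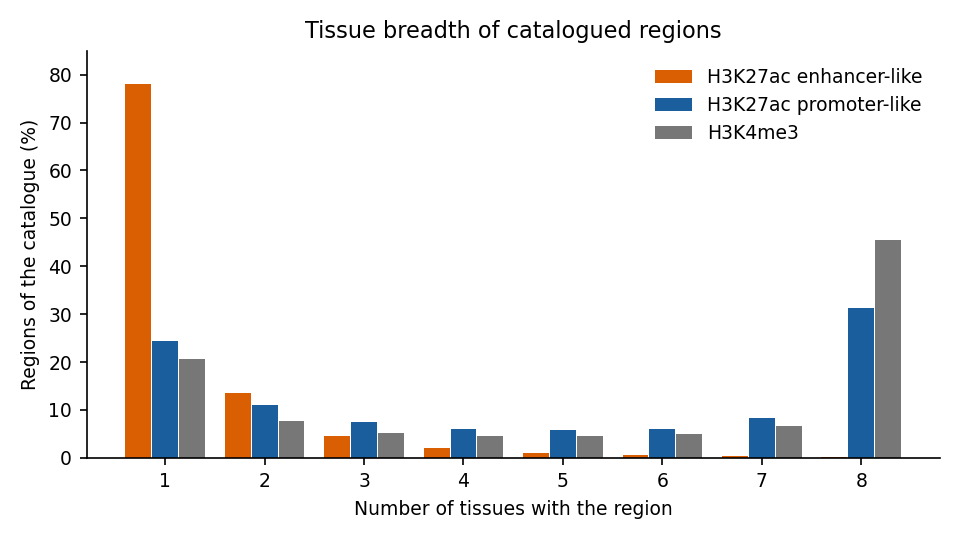
Percent of catalogued regions (vertical axis) by the number of tissues in which the region was found (horizontal axis), for enhancer-like H3K27ac regions (orange, 41524), promoter-like H3K27ac regions (blue, 23637) and H3K4me3 regions (grey, 23034). A tissue counted only where the region was found in both replicates, apart from the single heart H3K4me3 library. Enhancer-like regions concentrate at 1 tissue (78.1%), whereas 31.3% of promoter-like and 45.6% of H3K4me3 regions lie at 8.

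The H3K27ac maps grouped by tissue. The Jaccard index, the length shared by both maps divided by the length in either, was 0.520 ± 0.041 for the 8 pairs of libraries from the same tissue and 0.312 ± 0.055 for pairs from different tissues (SD over pairs). The difference of 0.208 had p = 2e-05 (two-sided permutation test, 16 libraries, adjusted p = 0.0001), the smallest that 100000 relabellings can give. The ranges did not overlap: same-tissue pairs lay between 0.474 and 0.580 and different-tissue pairs between 0.210 and 0.449. H3K4me3 maps had a mean of 0.643 ± 0.108 for the 7 same-tissue pairs and 0.581 ± 0.058 for the 98 others (SD over pairs). Their difference of 0.062 was smaller but past the threshold (two-sided permutation test, 15 libraries, p = 0.00382, adjusted p = 0.0112), and the ranges overlapped. Without the 2 shortest H3K4me3 lists it was 0.105 (permutation test, 13 libraries, p = 4e-05). In skeletal muscle and pancreas the H3K4me3 index between replicates was 0.467 and 0.518, below the means of 0.551 and 0.573 with other tissues, and in skeletal muscle it was also below the 0.530 of H3K27ac. The index cannot exceed the ratio of the covered lengths. Replicates 1 and 2 covered 12.8 Mb and 25.1 Mb in skeletal muscle and 12.8 Mb and 23.9 Mb in pancreas. These low values therefore need not mean that the maps were unlike. In the rest of the 7 tissues the H3K4me3 index between replicates exceeded the mean with other tissues, in spleen at 0.661 against 0.568. On the log2 scale the same-tissue index exceeded the mean of other tissues by 0.77 ± 0.19 in H3K27ac and by 0.13 ± 0.22 in H3K4me3 (SD, n = 7). H3K27ac had the larger ratio in 7 of 7 tissues, with a difference of 0.64 ± 0.30 (two-sided exact sign-flip permutation test, p = 0.0156, adjusted p = 0.0173). Without the short pancreas and skeletal muscle H3K4me3 lists it was 0.54 in 5 tissues, where p cannot go below 0.0625. With the 20000 strongest peaks of each list it was 0.53 (exact permutation test, n = 7, p = 0.0156). H3K4me3 covered more in replicate 2 in 7 of 7 tissues, so part of the difference between marks could follow from unequal lists.

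**Figure D3:**
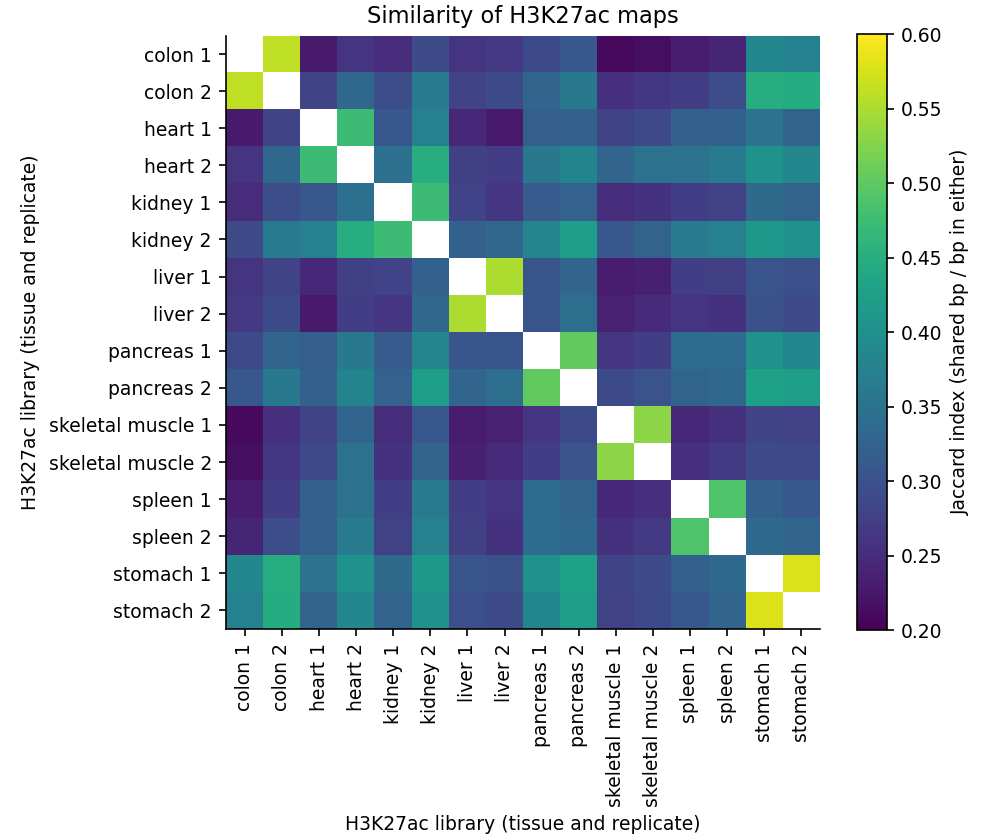
Jaccard index of H3K27ac maps between all pairs of the 16 libraries, with tissue and replicate number on both axes and the index as colour (no unit). Bright cells beside the empty diagonal are replicates of one tissue, which lie between 0.474 and 0.580, and all remaining cells lie between 0.210 and 0.449.

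Colon and stomach, which share gut mucosa and smooth muscle, had the most similar H3K27ac maps of any 2 different tissues, with a Jaccard index of 0.415 that ranked 1 of 28 tissue pairs. Heart and skeletal muscle, which share striated muscle, had 0.313 and ranked 14 of 28. These related pairs, fixed before the data were examined, averaged 0.364 against 0.308 for the others, a difference of 0.055 that did not pass the test (two-sided exact permutation test over 210 arrangements of 8 tissues, p = 0.114, adjusted p = 0.114). Pancreas with stomach (0.410) and kidney with stomach (0.371) followed colon with stomach. Skeletal muscle was the most distant partner of colon (0.236) and of liver (0.238).

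At a scale of 100 kb, windows marked in 1 tissue alone were more numerous than windows marked in 2 libraries of different tissues alone. Of 29670 windows 21986 held H3K27ac in at least 1 library. The number marked in both libraries of a tissue and in none of the other 14 was 478 in liver, 300 in skeletal muscle, 242 in colon, 207 in pancreas, 199 in kidney, 114 in spleen, 81 in stomach and 45 in heart. The mean of these same-tissue pairs was 208 ± 138, against 7.61 ± 6.66 windows for pairs of libraries from different tissues treated alike (SD over pairs), whose highest count was 28. The difference of 201 windows had p = 2e-05 (two-sided permutation test, 16 libraries, adjusted p = 0.0001). On assembled chromosomes alone it was 183 (permutation test, p = 2e-05). Liver also had the longest H3K27ac lists and heart the shortest, so the order of tissues may in part follow list length.

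The largest clusters of tissue-restricted H3K27ac regions, joined where they lay within 12 kb, are given by position on calJac3. Whether a gene lies there was not analysed here. Of the 24 clusters, 3 per tissue, 19 held no H3K27ac in any of the 14 libraries of other tissues. The first colon cluster had the highest coverage of all 24 and lay at chromosome 5, 108814664 to 108846687, where H3K27ac covered 13.8 ± 2.40 kb (SD, n = 2) of a 32.0 kb span and the replicates of H3K4me3 covered 6.56 kb and 9.17 kb. The first liver cluster, at chromosome 15, 62790670 to 62810110, held 11.5 ± 1.95 kb of H3K27ac (SD, n = 2) and no H3K4me3 in either liver library. The first skeletal muscle cluster, at chromosome 19, 22705080 to 22728051, held 11.5 ± 0.16 kb (SD, n = 2), with H3K4me3 in replicate 2 alone (5.38 kb). In pancreas the first cluster spanned chromosome 8, 103797970 to 103811025, with 8.35 ± 1.17 kb, and in spleen chromosome 2, 66915261 to 66931586, with 8.91 ± 2.96 kb (SD, n = 2 each). With the 20000 strongest peaks of each list the pancreas cluster held 5.52 kb. The first kidney cluster was at chromosome 12, 29472894 to 29486603, with 6.95 ± 0.86 kb, and the first stomach cluster at chromosome 15, 3409449 to 3426836, with 6.19 ± 1.89 kb (SD, n = 2 each). The first heart cluster was the smallest of the first clusters, at chromosome 8, 3264836 to 3270941, with 2.66 ± 0.38 kb (SD, n = 2). The spleen cluster had H3K27ac in 1 library of another tissue (0.426 kb), as did the heart cluster (0.305 kb). H3K4me3 of another tissue lay in 7 of the 24 clusters, among them the first clusters of stomach (at most 3.69 kb in a library), spleen (2.53 kb, against 0.897 kb and 1.41 kb in spleen), heart (2.52 kb, against 1.69 kb in heart) and colon (0.945 kb). These clusters were chosen for their restriction, so their absence elsewhere is a description and not a test.

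**Figure D4:**
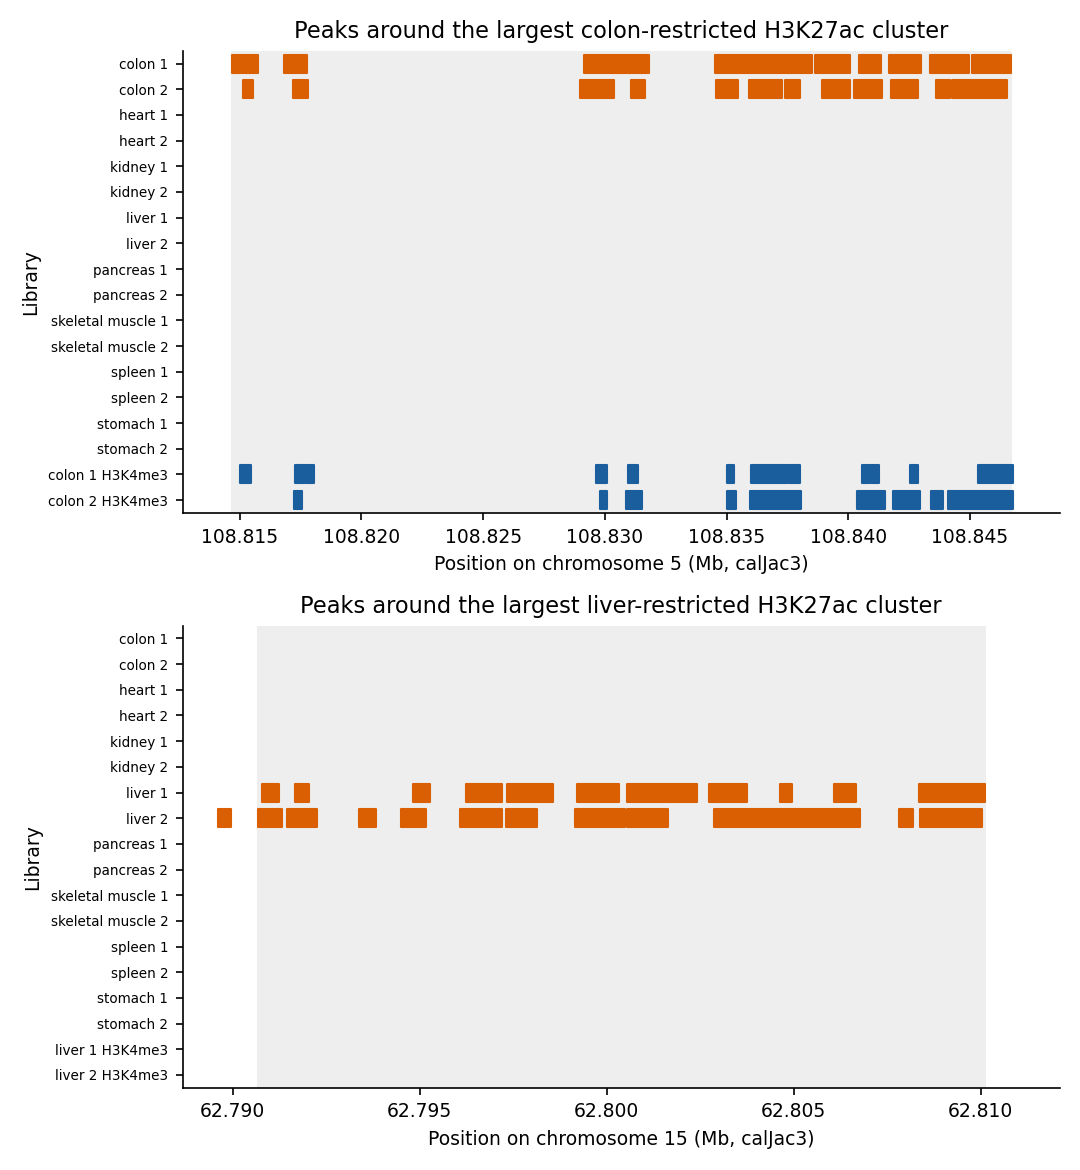
Peaks in the largest restricted cluster of colon (chromosome 5, top) and of liver (chromosome 15, bottom), with position in Mb on the horizontal axis and libraries on the vertical axis. Orange blocks are H3K27ac peaks of all 16 libraries, blue blocks H3K4me3 peaks of the cluster's own tissue, and grey shading is the cluster span. H3K27ac appears in both own libraries and in 0 of the 14 others.

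Most H3K4me3 regions also carried H3K27ac. In the 7 tissues with replicates, 15.1 ± 4.50% of reproducible H3K4me3 regions were overlapped by no H3K27ac region of the same tissue (SD, n = 7), from 9.09% in liver to 21.0% in stomach. Of these regions without H3K27ac, 72.9 ± 10.1% carried it in at least 1 library of another tissue (SD, n = 7). No such share is given here for H3K4me3 regions with H3K27ac, so this value cannot be called particular to those without. Regions with H3K27ac were longer than those without by a median of 478 ± 92.6 bp in 7 of 7 tissues (SD, n = 7; two-sided exact sign-flip permutation test, p = 0.0156). Longer regions are more easily overlapped by H3K27ac, so part of this length difference may follow from the overlap rule. With the 20000 strongest peaks of each list, which shortens the H3K27ac lists most, the share without H3K27ac was 23.3%.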

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

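Both results here rest on tests chosen after the values were seen. H3K4me3 lists were longer in replicate 2 than in replicate 1 in 7 of 7 tissues (log2 difference 0.23 ± 0.19, SD, n = 7; two-sided exact permutation test, p = 0.0156), and H3K27ac lists were not (-0.07 ± 0.12, SD, n = 8; p = 0.156). What drew attention is that the marks differed in this contrast, by 0.29 ± 0.24 log2 units (SD, n = 7; exact permutation test, p = 0.0156). It was 0.10 with the 20000 strongest peaks of each list (exact permutation test, p = 0.125), and 0.19 without the 2 shortest H3K4me3 lists, where 5 tissues cannot go below p = 0.0625. In covered length the marks differed by 0.46 ± 0.44 log2 units (SD, n = 7; exact permutation test, p = 0.0469). With 7 tissues it was 0.38 with the 20000 strongest peaks (exact permutation test, p = 0.0781), and it was 0.29 without the 2 shortest H3K4me3 lists (n = 5, p = 0.188, exact permutation test). Leaving out any library of colon, liver, pancreas, skeletal muscle, spleen or stomach removed its tissue from the contrast and gave 0.37 to 0.53 with p of 0.0625 or 0.0938, whereas leaving out a kidney library gave 0.55 (exact permutation tests, n = 6). Neither result was adjusted for the number of contrasts examined.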

How the results depend on the processing

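Of 58 values of the planned comparisons under alternatives able to move them, 54 kept their direction and their side of the threshold, and 246 of 246 did so with 1 library left out. The second count is weak evidence of stability. Most of the 246 came from sign-flip tests with all tissues on 1 side, where leaving out 1 library could hardly change the call. Values also repeated where leaving out different libraries dropped the same tissue. The exceptions among the 58 were peak number (0.072, p = 0.0625) and covered length (0.11, p = 0.148) by mark with the 20000 strongest peaks, where list lengths are nearly set equal by construction, and replicate overlap by mark (-14.9) and the similarity drop by mark (0.54) without the 2 shortest H3K4me3 lists, where 5 tissues cannot go below p = 0.0625 (exact permutation tests). The last alternative, the central 300 bp, the matching for strength and length, the enhancer-like version of the related pairs, 3 of the replicate blocks and all alternatives for results outside the planned comparisons were chosen after seeing the data. Of those results 33 of 43 values kept their call or value, and 138 of 168 with 1 library left out, where 24 of the others were the contrast of replicate numbers in covered length. With 1 library left out, the class difference in replicate overlap ranged from -35.0 to -32.4 points, the class difference in restricted share from 21.2 to 26.5 points, the H3K27ac similarity difference from 0.197 to 0.223 and that of H3K4me3 from 0.043 to 0.089. The related pairs stayed short of the threshold in every alternative. With the 20000 strongest peaks 11 of 24 clusters moved beyond their replicate spread; the other settings left nearly all cluster values untouched or, with 1 of 2 replicates left out, could not move them that far. The class difference of single tissues moved beyond its replicate spread in 7 of 8 tissues when matched for strength (heart -44.2 to -23.8, liver -28.3 to -10.7 points; colon, -25.8 to -11.6, stayed within it), in 3 of 49 values under other alternatives and in 0 of 14 with an H3K4me3 library of the same tissue left out.

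Replicate differences did not correlate between tissues beyond 0.042 in H3K27ac (28 tissue pairs, lowest -0.011) or 0.198 in H3K4me3 (21 pairs, lowest 0.008, 4 over 0.1), so correlation over 0.1 in every pair, the mark of pairing used here, was not reached and the blocks below stayed alternatives. This does not rule out a shared source, and a small set of regions did follow the number. With the replicate number as a block, peak number differed by 0.81 and covered length by 0.53 log2 units between marks. Their units were 15 pairs of marks of the same tissue and number, so replicates of a tissue were counted as separate units. Replicate overlap differed by -32.4 points and restricted share by 23.2 points between classes. There the class was set by H3K4me3 of the same number, and tissues stayed the units. The Jaccard index differed by 0.211 in H3K27ac and 0.079 in H3K4me3, with pairs taken across numbers only. Blocks added later gave 0.056 for the related pairs (p = 0.105, exact permutation test, n = 8), 0.62 for the similarity drop by mark and 202 for the windows, and none of the 9 changed a call. The blocks for peak number, covered length and the class differences do not show whether these would hold with a source shared by libraries of 1 number. Replicate overlap by mark compares the numbers themselves and had no block. The gene list alternatives and those on gene windows were not run, because no annotation of calJac3 was used here. Depth is unknown, so how far list length follows it was not tested.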

Other observations

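H3K27ac regions were sparse on the X chromosome. The catalogue held 8.69 regions per Mb on X and 23.6 per Mb on the autosomes, with enhancer-like regions making up 47.2% and 64.4%. Chromosome 22 was the densest autosome, at 50.4 regions per Mb, 43.3% of them enhancer-like. Chromosome length was taken as the end of its last peak, and these densities were not tested.

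Tests in the following paragraphs were chosen after the values were seen, with these exceptions: the Jaccard index of the related pairs, the class difference in replicate overlap and its matching for strength alone were fixed before the data were examined, and the matching for strength and length and the test with the 20000 strongest peaks on shared enhancer-like regions were set down before their results were known. Enhancer-like regions found in exactly 2 tissues (5610 of 41524) lay in related tissues more often than predicted by the tissue totals of these 5610 regions. Expected numbers were fitted to these totals. A high count in 1 pair therefore lowers the ratios of other pairs with the same tissues, which widens the contrast. Heart with skeletal muscle shared 151 such regions against 47.3 expected, rank 1 of 28 tissue pairs, and colon with stomach shared 949, 3.16 times the expected number, rank 2. The observed to expected ratio averaged 3.18 in these pairs and 0.86 in the others, a difference of 2.32 (two-sided exact permutation test over 210 arrangements of 8 tissues, p = 0.00952, the smallest possible). This was the third of 3 measures computed on these pairs. The planned Jaccard index and its enhancer-like version gave p = 0.114 and p = 0.133 in exact permutation tests, and the adjusted p of the third over all 3 was 0.0286. By the enhancer-like version colon with stomach ranked 1 of 28 (0.149). Heart with skeletal muscle ranked 18 of 28 (0.063), below the mean of 0.070 for the unrelated pairs. With the 20000 strongest peaks the difference in the observed to expected ratio was 1.91 (exact permutation test, p = 0.0381), which argues against weak peaks near the threshold as the whole source. A candidate explanation is that the pairs share cell types, which remains a hypothesis because the measure was chosen on the same data and no gene or cell marker was examined.

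The lower replicate overlap of enhancer-like regions was weighed against peak strength and length. The class difference of -33.9 points was -16.6 points within deciles of fold enrichment, -30.1 points when every region was reduced to its central 300 bp, and -15.7 points within strata of fold enrichment and length together (exact permutation tests, n = 8, p = 0.00781 each). About as much was lost with both properties matched as with strength alone, so strength may account for part of the difference. A difference stayed in each setting. The joint strata were coarser in strength than the deciles, and regions can still differ in strength within a stratum. How much of the rest follows from strength was therefore not settled. Whether the remainder reflects variation between animals, between tissue pieces or between preparations was not tested, since the labels name none of these. Nor was it tested how far it follows from the class rule, which leaves peaks called in error mostly among enhancer-like regions.

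A small set of regions followed the replicate number across tissues: in H3K27ac, 20 regions were found in all or all but 1 library of one number and in 0 of the other, 18 of them in replicate 2, and in H3K4me3 there were 69, of which 59 in replicate 2. Only the real assignment of numbers, 1 of 128 for H3K27ac and 1 of 64 for H3K4me3, gave as many, and the highest of the others gave 4 and 18, also when regions within 12 kb were counted once (15 and 66 loci); on assembled chromosomes alone there were 13 (highest other 4) and 34 (highest other 11), which argues against sequence outside them as the whole cause. With lists of equal length there were 8 (highest other 2), all in replicate 2, and 38 (highest other 6), 25 of them in replicate 2; 24 of the 69 H3K4me3 regions were among the 38, which argues against list length for these 24 and leaves it open for the other 45, whereas 2 of the 20 H3K27ac regions were among the 8, and what argues against length in H3K27ac is that replicate 2 had the longer list in 2 of 8 tissues. The run with the most such regions, on chromosome 4 from 3270312 to 3290843, was chosen after its values were seen: it contained 6 of the 20 H3K27ac regions, and held H3K27ac and H3K4me3 in 8 of 8 replicate 2 libraries of each mark and in 0 of the 8 and 7 replicate 1 libraries. Of the H3K27ac regions that carried any H3K4me3, 78.9% carried it in libraries of the same number alone (71.4% of 14 loci), so the numbers may mark the same 2 animals or batches in every tissue, and these cannot be told apart because the labels name neither; 35% of the H3K27ac regions lay outside assembled chromosomes against 2.98% of all regions, so differences in read placement stay open too.

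All 31 lists held peaks on the Y chromosome, from 18 to 53 per list. The share of peaks outside assembled chromosomes was higher in replicate 2, by 0.65 ± 0.52 percentage points in H3K27ac (8 of 8 tissues; exact permutation test, n = 8, p = 0.00781) and by 0.94 ± 0.56 points in H3K4me3 (7 of 7; n = 7, p = 0.0156).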
